A study of Mus musculus with 4 samples.

How the data were processed

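Gene expression was measured with microarrays in a mouse Th1 T cell clone, a line of CD4 helper T cells of the type that makes interferon gamma. The 4 arrays fall into 2 groups of 2 by their titles: resting cells of the normal clone (control arrays 1 and 2) and cells made anergic with plate-bound antibody against CD3 (anergic arrays 1 and 2). RNA was extracted with Trizol and made into biotin-labelled cRNA, per the labels' protocols. No label says that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical in part. The molecule is listed in the labels as polyA RNA.

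The deposited values are intensities on a linear scale, with 1 value for each of 12488 probe sets on each array. The scanner software, the background correction and the way probes were combined into a probe set value are not given in the sources used here. The deposited intensities had been scaled before deposit, as the values themselves show: the mean after trimming 2% of the values at each end was 500.3 on all 4 arrays. No array was a copy of another, since any pair of arrays shared between 12 and 18 identical values. Detection calls were not used here, so a low value was treated as measured. The array design itself limits precision through the number of arrays, 2 per group, and no depth is defined for it.

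Probe sets were named from GEO's platform annotation, and symbols were checked through gene IDs against a RefSeq gene table of the assembly GRCm38.p6, which was used for names and for the order of neighbouring genes. Of 12422 probe sets other than the 66 controls, 10833 had 1 gene symbol, 396 had several and 1193 were not listed. A current symbol was found by gene ID for 10817 of the first kind, and no symbol changed. Probe sets with several symbols and unlisted ones were tested but not named. No build is named for the array, so no coordinates are given.

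Intensities were transformed as log2(value + 29.15), where the pseudocount is the median over arrays of each array's 20th percentile. Fold changes are on this scale, which understates the change of genes with low values. The deposited scale was kept, since the trimmed means lay within 1.1-fold of each other, the limit set in advance. Control probe sets were left out, and probe sets were kept when their mean log2 value was above the 40th percentile, which left 7453. Anergic and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. A gene was represented by its probe set with the highest mean, giving 5583 genes, which were fitted in the same way. That probe set was kept in the alternatives wherever it passed the filter, except where the probe sets of a gene were averaged. This was decided after the results had been seen, because leaving out an array had otherwise changed the probe set of Cd6, Pik3cd, Slc19a1 and Slfn2 and ended the calls of the last 3, which hold with the probe set kept. All adjusted p-values of genes come from limma with Benjamini-Hochberg adjustment. Each gene fit had 2 residual degrees of freedom and borrowed 7.74 prior degrees of freedom from the other genes. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so the calls rest on this shared estimate of the spread.

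Gene lists were tested against all other genes with camera in limma, with the preset inter-gene correlation of 0.01, and the p-values of the 26 lists were adjusted together. Each list was also tested with a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance in a single direction. The lists, the test, the filter and the naming rule were fixed before the data were examined. The lists cover anergy-associated genes; proximal T cell receptor signalling; Ras, MAP kinase and AP-1; diacylglycerol and protein kinase C; Th1 identity; cytokines and chemokines; the cytotoxic granule; costimulatory and inhibitory receptors; T cell activation and cytokine receptors; and NFAT, NF-kB and immediate early genes. They also cover DNA replication and mitosis, cell cycle inhibitors and quiescence, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, ribosomal proteins, chaperones and the unfolded protein response, interferon-induced genes, apoptosis, and ubiquitin ligases with other negative regulators of signalling. The remaining lists hold markers of B cells, of macrophages and dendritic cells, of granulocytes and mast cells, of erythroid cells and platelets, of other T cell subsets and NK cells, and of fibroblasts and stroma.

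The genes named in the text are, in each direction, the 12 with the largest log2 difference among genes that passed the threshold with both anergic arrays on the same side of both control arrays; the up to 4 members of each list with the smallest p; and a fixed set of anergy and T cell genes (Egr2, Egr3, Dgka, Dgkz, Rnf128, Cblb, Itch, Ifng, Il2, Il2ra, Cd3e, Cd4 and Tbx21). Of that set, Egr3, Dgkz, Rnf128, Cblb and Tbx21 had no probe set with a single gene symbol and were not analysed here. Ccl5, Tgfb1, Ltb, Penk, Dusp6, Cd70, Tnfrsf8, Tmem109 and Slc29a1 fall outside this rule and were chosen after their values were seen. The same holds for probe sets of T cell receptor segments and the macrophage genes Lyz2, Cd74, Cd14, Csf1r and Adgre1. It holds as well for the interferon-induced genes Ifit3, Irgm1, Ifi47, Igtp, Psmb9, Psmb10 and Tap1. It also holds for the ligand genes Tnfsf11, Lta, Tnf, Cd40lg and Tnfsf10.

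Alternatives were a pseudocount of 1 or at the array median (161.2), quantile normalization, centring of each array on its median, no filter or a filter at the 60th percentile, eBayes without the trend or with robust fitting, treat with a minimum fold of 1.2, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array in turn. The scripts were tested on simulated data. Over 10 simulated comparisons of 2 arrays with 2 on the 7453 probe sets, limma recovered 7% of the probe sets changed by 1 on the log2 scale, 67.8% of those changed by 2, 87.2% of those changed by 3 and 95.6% of those changed by 4, and 4.87% of the calls were false. On the 5583 genes, a gene list shifted by 0.5 was called by camera in 20 of 20 simulations with the preset correlation and in 0 of 20 with an estimated correlation, and 0 lists were called where nothing was shifted. The simulated genes varied independently of each other, so these counts do not show how often a list whose members vary together is called falsely. The simulated spreads were drawn from limma's own model as fitted to these data, with no effect shared by arrays of the same number. The 4.87% therefore checks the scripts and does not measure the share of false calls among the real ones. A list call that ends with the estimated correlation can be a real shift or a false call. The simulations cannot tell these apart.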

Results

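T cell anergy is a state in which a T cell that has met its stimulus under unfavourable conditions, such as a T cell receptor signal without costimulation, responds poorly to the next one. The study asked which genes differ in expression between a resting mouse Th1 clone and the clone after it had been made anergic by antibody against CD3, the signalling part of the T cell receptor, fixed to a plate. The data are 12488 intensities on each of 4 arrays, 2 of control and 2 of anergic cells. Median intensities were 146.5 and 191.2 on control arrays 1 and 2. They were 134.2 and 175.8 on anergic arrays 1 and 2. Across the 7453 probe sets tested, Pearson's r was 0.925 between the control arrays and 0.944 between the anergic arrays. Between groups it was 0.924 for the arrays numbered 1 and 0.921 for those numbered 2. It was 0.891 and 0.887 for the pairs of unlike number. By the median absolute log2 difference, however, the closest pair was control array 2 with anergic array 2 (0.303). Control array 1 with anergic array 1 was at 0.361, against 0.378 between the control arrays and 0.337 between the anergic arrays. Arrays of the same number thus resembled each other across groups, which the main fit does not model. Limma called 100 probe sets between the groups, 14 when arrays numbered 1 were set against those numbered 2, and 0 in the remaining split into pairs. Control array 2 stood apart in its 9 bacterial spike-in control probe sets, whose geometric mean was 1972 there. It was 948.9 on control array 1, and 870.4 and 1014 on the anergic arrays. Bright transcripts of the cells were also higher on control array 2. The 3' control probe set was at 24098 for Gapdh there, against 13520 to 15842 on the other arrays. For Actb it was at 27573, against 15438 to 19857. The ratio of 3' to 5' signal, a measure of RNA integrity, was between 0.782 and 0.854 for Gapdh and between 0.97 and 1.35 for Actb. T cell identity genes were bright in both groups. Cd4 was at 4013 ± 101 (SD, n = 2) in control and 4846 ± 367 (SD, n = 2) in anergic cells (adjusted p = 0.72). The receptor chain gene Cd3e was at 8038 ± 2919 and 7543 ± 1039 (adjusted p = 0.966).

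With 1 probe set per gene, the chemokine gene Ccl9 and the receptor gene Crtam rose most in anergic cells, in an order that depends on the pseudocount. Ccl9 rose from 61.9 ± 33.9 to 11520 ± 1618 (SD, n = 2 each), a fold of 131 and a log2 difference of 7.03 ± 0.31 (SE, adjusted p = 5.71e-06). Crtam, an immunoglobulin-family receptor of activated T and NK cells, rose from 10.1 ± 2.4 to 2341 ± 124, a log2 difference of 5.92 ± 0.33 (SE, adjusted p = 2.64e-05). Cd6, a scavenger-receptor-family molecule that modulates T cell receptor signals, rose by 4.18 ± 0.32, and its other probe set by 6.42, more than Crtam. The chemokine gene Ccl1, the ligand of the receptor CCR8, was already at 1837 ± 1414 in control cells and reached 19234 ± 3546 (log2 difference 3.60 ± 0.45, SE). The adhesion molecule gene F11r rose by 3.73 ± 0.30 and Pdzk1ip1, which encodes a small membrane protein, by 4.24 ± 0.25. Genes known mainly from other tissues also rose: Iapp, encoding the islet hormone amylin, by 4.43 ± 0.61, and Scg2, encoding a granin of secretory granules, by 3.24 ± 0.50. Both were close to background in control cells (8.6 ± 1.4 and 17.1 ± 12.2, SD), as was Crtam, so the size of these differences depends on the pseudocount of 29.15, and Iapp differed between anergic arrays 1 and 2 (1589 and 378.7). The other genes among the 12 with the largest rise were the vesicle fusion gene Vamp5 (4.18), the LIM-domain gene Fhl2 (3.55), the kinase gene Hipk2 (3.30) and Slfn2 (3.29), a gene needed for T cell quiescence. The other probe set of Slfn2 rose by 2.02. Adjusted p-values of these 12 genes lay between 5.71e-06 and 0.00912. With the pseudocount at the array median the differences of the dimmer genes were smaller but still passed, at 3.87 for Crtam, 2.52 for Iapp, 2.76 for Vamp5, 2.14 for Hipk2 and 1.66 for Scg2. With a pseudocount of 1 Crtam was at 7.74 and Ccl9 at 7.62.

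**Figure D1:**
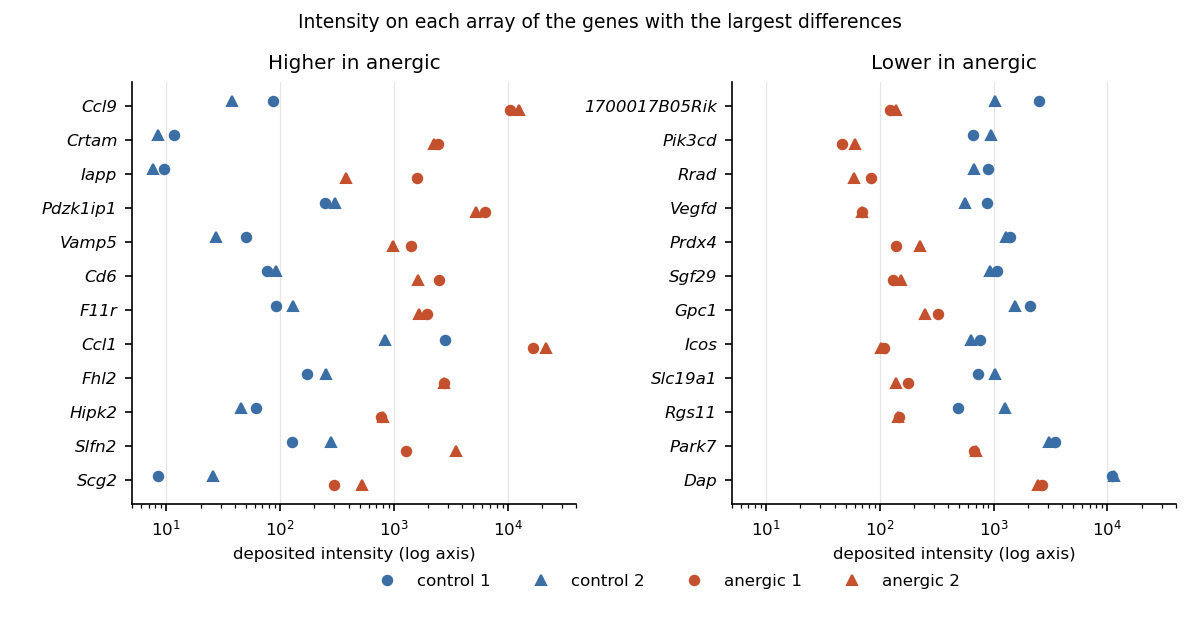
Deposited intensity on a log axis (horizontal) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in anergic cells, with 1 point per array, blue for control and red for anergic, circles for array 1 and triangles for array 2. The red and blue points of each gene do not overlap, and Ccl9 lies at 37.9 and 85.8 in control but at 10376 and 12664 in anergic cells.

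Genes that fell in anergic cells reached smaller differences. Pik3cd, which encodes the leukocyte p110-delta catalytic subunit of PI3-kinase, fell from 806 ± 212 to 53.5 ± 9.9 (SD, n = 2 each), a log2 difference of -3.32 ± 0.37 (SE, adjusted p = 0.00187), and its other probe set showed -1.74. Icos, a costimulatory receptor gene, fell from 697 ± 87.8 to 106 ± 4.9, a log2 difference of -2.42 ± 0.33 (SE, adjusted p = 0.0048). The peroxiredoxin gene Prdx4 (-2.73 ± 0.31) and the oxidative stress gene Park7 (-2.19 ± 0.24) both fell. Dap, a gene linked to cell death and autophagy, was bright and fell from 11132 ± 256 to 2570 ± 140. Slc19a1, the folate carrier gene, fell by 2.28 on the log2 scale, with -0.41 at its other probe set. The remaining genes among the 12 were 1700017B05Rik (-3.36), the growth factor gene Vegfd (-2.87), Sgf29, which encodes a chromatin reader (-2.60), the proteoglycan gene Gpc1 (-2.54) and the G protein regulator gene Rgs11 (-2.20). The small GTPase gene Rrad, also among them, fell from 780 ± 152 to 71.9 ± 17.1. Rgs11 lost its call without control array 2 (-1.54, adjusted p = 0.0634), without anergic array 1 (-2.22, adjusted p = 0.0556) and with quantile normalization (-2.21, adjusted p = 0.0718), and Slc19a1 with the mean of its probe sets (-1.34, adjusted p = 0.0563). With the pseudocount at the array median Pik3cd was at -2.16 and Vegfd at -1.90, and both passed.

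Over all 7453 probe sets, 68 were higher and 32 lower in anergic cells in limma after Benjamini-Hochberg adjustment, and each of these 100 differed by at least 2-fold. The smallest difference that passed was 1.21 on the log2 scale, and 839 probe sets had an unadjusted p under 0.05. In 3001 probe sets (40.3%) the arrays of both groups did not overlap, where chance alone gives 33.3%. At the level of genes, 74 of 5583 were higher and 47 lower. Of these, 17 rose by at least 8-fold and 14 fell by at least 4-fold. Of 18 such genes with more than 1 tested probe set, 16 had all of them in the same direction. The exceptions were Tnfrsf9 (2.64 and -0.22) and the nucleoside transporter gene Slc29a1 (1.79 and -1.29), which was at 0.25 with the mean of its probe sets (adjusted p = 0.894) and lost its call without anergic array 1 (1.68, adjusted p = 0.13). Centring each array on its median gave 52 higher and 12 lower probe sets in place of 68 and 32. The median log2 difference of all tested probe sets was -0.0855 on the deposited scale and 0.0209 after this centring.

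**Figure D2:**
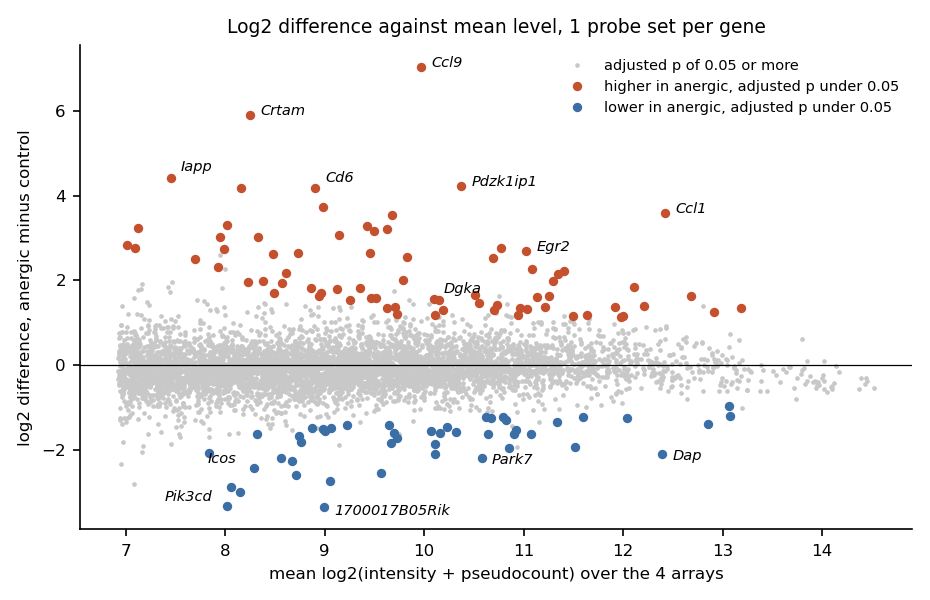
Log2 difference, anergic minus control (vertical), against the mean log2(intensity + pseudocount) over the 4 arrays (horizontal), with 1 point for each of 5583 genes. Red points mark the 74 genes that were higher and blue points the 47 that were lower at an adjusted p under 0.05; Ccl9 lies at the top at 7.03 and 1700017B05Rik at the bottom at -3.36.

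Genes known from anergy rose in part. Among 16 measured members of the list of anergy-associated genes, Crtam, Egr2, Dgka and Tnfrsf9 rose, Ptpn6 fell and 11 did not pass. Adjusted over the list alone, 5 rose and 1 fell. Egr2, a transcription factor gene induced by NFAT in anergic T cells, rose from 807 ± 211 to 5708 ± 3120 (SD, n = 2 each), a log2 difference of 2.69 ± 0.37 (SE, adjusted p = 0.0048). Dgka, the diacylglycerol kinase gene that removes the lipid messenger needed for Ras activation, rose from 620 ± 183 to 1857 ± 163 (log2 difference 1.57 ± 0.28, SE, adjusted p = 0.0215). Tnfrsf9, encoding the costimulatory receptor 4-1BB, rose by 2.64 ± 0.36. Ptpn6, encoding the inhibitory phosphatase SHP-1, fell by 1.42 on the log2 scale (adjusted p = 0.0298). The ubiquitin ligase gene Itch, also tied to anergy, differed by -0.32 ± 0.29 (adjusted p = 0.764). Camera called the list higher than other genes (adjusted p = 0.0078, median 0.183, mean 0.752), with adjusted p = 0.803 with an estimated correlation. By sign 9 members were higher and 7 lower in anergic cells, so the call rests largely on the few with large rises. The calls of Dgka and Ptpn6 were lost without either anergic array, but their differences hardly moved. Without anergic array 1 the difference was 1.48 ± 0.409 (SE) for Dgka and -1.42 ± 0.405 for Ptpn6. Without anergic array 2 it was 1.65 ± 0.404 and -1.43 ± 0.401. With all arrays both SEs were 0.28. These losses thus came with the wider SE of a fit with 1 anergic array, whose residual spread comes from the control arrays alone. Tnfrsf9 was at 1.21 with the mean of its probe sets (adjusted p = 0.135), and Ptpn6 also missed the threshold with quantile normalization (-1.39, adjusted p = 0.0526). The list's median was 0.0828 and 0.43 without control array 1 and 2, and 0.376 and -0.0354 without anergic array 1 and 2, and camera called it higher each time.

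Several chemokine genes rose. Of 20 measured cytokines and chemokines, Ccl1, Ccl3, Ccl4, Ccl5, Ccl9 and Tgfb1 rose, Ltb fell and 13 did not pass. Among the 13 is Penk (0.63, adjusted p = 0.374), whose dimmer probe set rose (adjusted p = 0.00125 over probe sets). Adjusted over the list alone, 10 rose and 3 fell. Ccl3 and Ccl4, which encode inflammatory chemokines, rose by 2.77 ± 0.24 (SE, adjusted p = 0.000474) and 3.03 ± 0.41 (SE, adjusted p = 0.00442). Ccl5 was at 5839 ± 1093 (SD, n = 2) in control cells and rose 2.56-fold, and the gene of the suppressive cytokine Tgfb1 rose 2.68-fold. Ltb, encoding lymphotoxin beta, fell by 0.98 on the log2 scale (adjusted p = 0.0493). Camera placed the list above other genes (adjusted p = 7.26e-08, median 0.725), with adjusted p = 0.803 with an estimated correlation. Ifng, the main Th1 cytokine gene, was at 2391 ± 366 in control and 4366 ± 704 in anergic cells (SD, n = 2 each), a log2 difference of 0.86 ± 0.24 (SE, adjusted p = 0.132). Il2 stayed below the filter, with values between 2.8 and 6 on the 4 arrays. Leaving out anergic array 1 or 2 ended the calls of Tgfb1 (1.38 and 1.46, adjusted p = 0.13 and 0.0696), Ccl5 (1.47 and 1.24, adjusted p = 0.13 and 0.215) and Ltb (-0.93 and -1.02, adjusted p = 0.56 and 0.384).

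Surface receptors moved in both directions. In the list of costimulatory and inhibitory receptors, Tnfrsf18 (GITR) rose by 1.84 ± 0.23 (SE, adjusted p = 0.00334), Tnfrsf9 by 2.64 and the inhibitory ligand gene Cd200 by 1.71. Icos fell by 2.42 on the log2 scale and 11 of 15 did not pass. Over the list alone 3 rose and 1 fell, and camera gave adjusted p = 0.0952. Among 14 T cell activation and cytokine receptors the integrin gene Itgb2 rose by 1.63 ± 0.23. Il7r, the receptor gene for the survival cytokine IL-7, fell from 2461 ± 1393 to 506 ± 29.5 (SD, n = 2 each; log2 difference -2.10, adjusted p = 0.0191). The other 12 did not pass, among them Il2ra (1.17 ± 0.36, adjusted p = 0.17). Adjusted over the list alone 3 rose and 1 fell, and camera gave adjusted p = 0.658. In the Th1 identity list Ifngr1, an interferon gamma receptor gene, fell by 1.87 and the chemokine receptor gene Cxcr3 by 1.55 on the log2 scale (adjusted p = 0.024 and 0.0332). The other 11 of 13 did not pass, including Irf1 (-0.87, adjusted p = 0.148). Adjusted over the list alone 1 rose and 3 fell, with adjusted p = 0.657 by camera. Quantile normalization ended the calls of Ifngr1 (-1.91, adjusted p = 0.0728) and Il7r (-2.11, adjusted p = 0.0683). Leaving out anergic array 1 ended those of Cxcr3 (-1.27, adjusted p = 0.271), Cd200 (1.72, adjusted p = 0.132) and Itgb2 (1.65, adjusted p = 0.0537). Leaving out anergic array 2 ended those of Ifngr1 (-1.32, adjusted p = 0.112), Cd200 (1.71, adjusted p = 0.0879) and Itgb2 (1.61, adjusted p = 0.0563).

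Few signalling genes passed the test. Of 21 proximal T cell receptor signalling genes Cd6 rose and 20 did not pass, among them the adaptor gene Lcp2 at 0.76 ± 0.22 (SE, adjusted p = 0.135). The median of the list was -0.0493 and its mean 0.215, and camera gave the upward direction without passing (adjusted p = 0.351). None of 21 genes of the Ras, MAP kinase and AP-1 list passed in limma, where 6 had an unadjusted p under 0.05 (adjusted p = 0.932 by camera). Of these 6, 3 were higher and 3 lower in anergic cells. There Map2k1 differed by 0.89 ± 0.24 and Junb by 1.64 ± 0.49, while Rasa3 differed by -1.06 ± 0.34 and Fos by -1.14 ± 0.37 (SE). In the list of diacylglycerol and protein kinase C, Dgka rose and 14 did not pass, among them Prkcd at 0.84 ± 0.24 (adjusted p = 0.133). Over the list alone 2 rose, and camera gave adjusted p = 0.102. Of 29 NFAT, NF-kB and immediate early genes, Egr2, Ier3 (2.56 ± 0.28, SE) and Nfkb2 (1.46 ± 0.24, SE) rose, Myc and Dusp6 fell, and 24 did not pass. Over the list alone 8 rose and 4 fell, and camera gave adjusted p = 0.0784. Myc, a driver of T cell growth, fell from 447 ± 98.2 to 84 ± 24.8 (SD, n = 2 each). Among ubiquitin ligases and negative regulators Map4k1, an inhibitory kinase gene, rose by 1.98 and Rgs16 by 1.66, while Ptpn6, Sit1 and Dusp6 fell. The other 20 of 25 did not pass, and 4 rose and 4 fell over the list alone (camera adjusted p = 0.658). The NFAT, NF-kB and immediate early list was called higher with no filter on low values (adjusted p = 0.0191) and with the stricter filter (adjusted p = 0.0156). It was also called without control array 1 (adjusted p = 0.000111), without anergic array 2 (adjusted p = 0.00338) and with the replicate number as a block (adjusted p = 0.0478). It did not pass without anergic array 1 (adjusted p = 0.505), without control array 2 (adjusted p = 0.159), with quantile normalization (adjusted p = 0.273), with centring (adjusted p = 0.288) or with an estimated correlation (adjusted p = 0.803). Leaving out 1 array ended the calls of Nfkb2 (1.53 and 1.39 without anergic array 1 and 2) and Myc (-1.85 without anergic array 1 and -1.86 without control array 2). The same was true of Dusp6 (-1.06 without anergic array 2), Rgs16 (1.68 without anergic array 1) and Sit1 (-1.41 without anergic array 1 and -1.18 without control array 1). With quantile normalization Dusp6 (-1.62, adjusted p = 0.098) and Sit1 (-1.54, adjusted p = 0.0807) did not pass, and with the pseudocount at the array median Myc was at -1.31 and passed.

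Proliferation genes did not pass as a group, and the call of the glycolysis list depended on the settings. Of 32 DNA replication and mitosis genes 0 passed in limma, where 6 had an unadjusted p under 0.05. Adjusted over the list alone Lig1 (-1.25 ± 0.33, SE), Pola1 (-1.40 ± 0.34, SE) and Hmgb2 (-1.48 ± 0.33, SE) fell, and camera gave adjusted p = 0.619. Among 22 cell cycle inhibitors and quiescence genes Slfn2 rose, Txnip fell by 1.23 on the log2 scale (adjusted p = 0.0232), and 20 did not pass, including Cdkn1a (1.07 ± 0.28, adjusted p = 0.108). In that list 5 rose and 2 fell over the list alone, and camera gave adjusted p = 0.266. Of 17 glycolysis genes Hk2, the hexokinase gene induced in growing T cells, fell from 1966 ± 87.1 to 664 ± 304 (SD, n = 2 each; log2 difference -1.60, adjusted p = 0.0338) and 16 did not pass. Over the list alone 1 rose (Pfkm, 1.55 ± 0.34) and 3 fell (Hk2, Pkm at -0.81 ± 0.21 and Pdk1 at -1.33 ± 0.33). Camera called the glycolysis list lower (adjusted p = 0.0233, median -0.37), but not with an estimated correlation (adjusted p = 0.952) or by fry (adjusted p = 0.74). That call was lost without control array 2 (median -0.11, adjusted p = 0.9) and without anergic array 2 (median -0.239, adjusted p = 0.321), while without control array 1 the median was -0.742. The call of Hk2 was lost without anergic array 2 (-1.14, adjusted p = 0.219), and that of Txnip without anergic array 1 (-1.19, adjusted p = 0.232) or 2 (-1.27, adjusted p = 0.138). With quantile normalization Hk2 was at -1.63 (adjusted p = 0.0888), and with the mean of its probe sets Txnip was at -0.80 (adjusted p = 0.186).

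Camera with the preset correlation called ribosomal protein and interferon-induced genes lower as groups, with few or no single genes passing. All 21 measured ribosomal protein genes had a negative difference, between -1.02 and -0.10, and none passed in limma, alone or over the list, where 8 had an unadjusted p under 0.05. Rps19 differed by -1.02 ± 0.34, Rpsa by -0.67 ± 0.22 and Rpl8 by -0.62 ± 0.23 (SE). Camera called the ribosomal list lower (adjusted p = 2.68e-06, median -0.515), with adjusted p = 0.803 with an estimated correlation. Of 29 interferon-induced genes, the exonuclease gene Isg20 (-1.63 ± 0.24, SE) and Irf9, a subunit of the type I interferon transcription factor (-1.47 ± 0.26, SE), fell. The other 27 did not pass, among them Ifit1 (-2.80 ± 0.69, adjusted p = 0.0854) and Iigp1 (-1.62 ± 0.41, adjusted p = 0.0887). Adjusted over the list alone, 0 rose and 5 fell. Camera called the list lower (adjusted p = 2.72e-05, median -0.58), with adjusted p = 0.803 with an estimated correlation. Control array 2, the array with the spike-in mean of 1972, weighed on both lists. Without it the ribosomal median was -0.292 (adjusted p = 0.00958) and the interferon median -0.239 (adjusted p = 0.159). Quantile normalization brought the ribosomal median to -0.136 (adjusted p = 0.00412), and the pseudocount at the array median brought the interferon median to -0.38. The calls of Isg20 and Irf9 were lost without anergic array 1 (-1.57 and -1.63, adjusted p = 0.0556 and 0.0503), and that of Irf9 without anergic array 2 (-1.31, adjusted p = 0.12).

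**Figure D3:**
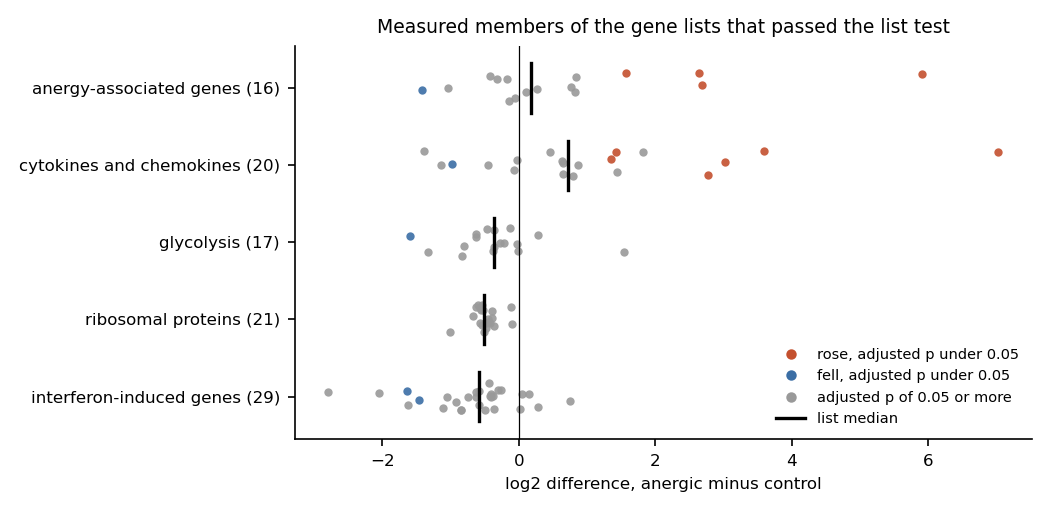
Log2 difference, anergic minus control (horizontal), of each measured member of the 5 gene lists that passed camera with the preset correlation, with the number of measured members in brackets. Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and black bars mark the medians, from -0.58 for interferon-induced genes to 0.725 for cytokines and chemokines; vertical scatter within a list has no meaning.

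Lists for other metabolic and survival programmes, and for other cell types, did not pass camera. None of 32 oxidative phosphorylation genes, 16 cholesterol biosynthesis genes, 30 chaperone and unfolded protein response genes, 22 apoptosis genes and 9 cytotoxic granule genes passed in limma. At an unadjusted p under 0.05 there were 1, 2, 8, 1 and 0 of them, and the camera adjusted p-values of these lists were 0.658, 0.671, 0.863, 0.824 and 0.7. The heat shock gene Hspa1b differed by 2.26 ± 0.50 (SE, adjusted p = 0.0522), and 3 chaperone genes rose and 1 fell when adjusted over the list alone. Among markers of macrophages and dendritic cells Cd68, a lysosomal membrane protein gene that other leukocytes also express, rose by 2.31 ± 0.36 (SE, adjusted p = 0.0103) while 11 of 12 did not pass, including Ctss at -0.86 ± 0.45 (camera adjusted p = 0.804). The call of Cd68 was lost without anergic array 1 (2.35, adjusted p = 0.0609) or 2 (2.26, adjusted p = 0.063), and its difference was 1.48 with the pseudocount at the array median. None of the 8 B cell markers, 6 granulocyte and mast cell markers, 4 erythroid and platelet markers, 4 markers of other T cell subsets and NK cells and 6 fibroblast and stromal markers passed over all genes in limma. There 2 fibroblast markers and 0 of the others had an unadjusted p under 0.05. Over the list alone 1 fibroblast marker, Lum, rose (0.97 ± 0.26, adjusted p = 0.115 over all genes). Camera gave these lists adjusted p-values of 0.619, 0.657, 0.932, 0.998 and 0.998. Of all 26 lists, 8 had an unadjusted camera p under 0.05, 5 passed after adjustment, and 0 passed with an estimated correlation or with fry.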

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

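Counts of called probe sets moved most with the replicate number as a block (761 calls against 100). They also moved with single arrays and with the model of the spread. The counts of probe sets higher, lower and changed at least 2-fold in anergic cells were 68, 32 and 100. They were 62, 28 and 90 with a pseudocount of 1, 66, 32 and 98 with it at the array median, 67, 28 and 93 with quantile normalization, 55, 26 and 81 with the stricter filter and 70, 36 and 106 with robust eBayes. Centring on the median gave 52, 12 and 64, no filter 42, 17 and 59, and no intensity trend 28, 10 and 38, while treat with a minimum fold of 1.2 gave 63. Leaving out 1 array gave 26 to 208 higher, 17 to 136 lower and 43 to 323 changed at least 2-fold. The lowest counts came without anergic array 1 (26 and 17), and the highest without control array 2 (208 and 136). The residual spread then comes only from the pair left in the other group, and the lone array is assumed to vary like that pair. By the median absolute log2 difference the control arrays lay further apart (0.378) than the anergic arrays (0.337). Of the 100 probe sets, 100 and 99 were shared without control array 1 or 2, 38 and 53 without anergic array 1 or 2, 87 with quantile normalization and 38 without the intensity trend. For Tgfb1, Itgb2, Nfkb2 and Cd68 the difference hardly moved without an anergic array, while its SE grew. For Itgb2 the SE was 0.231 with all arrays, and 0.383 and 0.392 without anergic array 1 and 2. Differences of Dusp6, Hk2 and Ifngr1 were smaller without anergic array 2, and that of Cxcr3 without anergic array 1. Whether the source of the residual spread accounts for all of the changed counts was not tested.

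The replicate number as a block gave 389 higher, 372 lower and 405 changed at least 2-fold, with all 100 probe sets among its 761. Deviations of same-numbered arrays from their group means correlated at 0.537 across probe sets, but no label says that equal numbers share a culture or a day, and there are only 2 pairs.

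The number of gene lists called was 5, between 4 and 6 in the alternatives with the preset correlation, and 0 with an estimated correlation and with fry. The anergy, cytokine and ribosomal lists passed in every setting with the preset correlation. The interferon list failed without control array 2, and glycolysis failed there, without anergic array 2, without the trend (adjusted p = 0.0832) and without the filter (adjusted p = 0.0634). Costimulatory and inhibitory receptors passed without control array 2 (adjusted p = 0.0347).

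Of 80 genes followed through the alternatives, 55 passed in limma, 29 of them in every alternative with all arrays in which they were tested and 28 in every alternative in which they were tested. Of the 28, 20 were tested in all 14 alternatives and 8 fell below the filter in at least 1, most often the stricter filter. Calls lost numbered 23 without the trend, 15 with centring, 9 without the filter, 7 with quantile normalization, 18 and 15 without anergic array 1 or 2, and 1 and 2 without control array 1 or 2. Without the trend (adjusted p between 0.0551 and 0.233) these were Egr2, Slfn2, Dgka, Ccl5, Tgfb1, Ltb, Cd200, Itgb2, Ifngr1, Cxcr3, Il7r, Nfkb2, Dusp6, Txnip, Hk2, Isg20, Irf9, Rgs16, Ptpn6, Sit1, Rgs11, Tmem109 and Slc29a1. Centring (adjusted p between 0.071 and 0.333) ended the calls of the same genes other than Egr2, Slfn2, Ccl5, Cd200, Itgb2, Rgs11, Tmem109 and Slc29a1. Tnfrsf9 lost its call with the mean of its probe sets (1.21, adjusted p = 0.135). Cd3e, which did not pass, changed sign with centring on the median (0.057), and ranged from -0.43 to 0.33 when 1 array was left out. The alternative of keeping the deposited scale is the setting used throughout, and robust eBayes was not run for gene lists. Intensities near the pseudocount of 29.15 limit how well low genes can be compared.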

Other observations

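The tests of the macrophage and the interferon gamma explanations were chosen after part of the values they use had been seen; the others were set before. The grouping of genes by symbol, the count of neighbours and the repeat of the ribosomal test after quantile normalization were also chosen after the data had been examined. All bootstrap intervals below resample the genes of a list, which are not independent replicates. They measure the spread among genes and not that between arrays.

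Tnfrsf8 and Cd70, which are outside the fixed lists, also rose. Tnfrsf8, encoding CD30, rose from 58 ± 6 to 680 ± 107 (SD, n = 2 each), a log2 difference of 3.02 ± 0.36 (SE, adjusted p = 0.00229 in limma), or 1.93 with the pseudocount at the array median. Cd70, the ligand gene of CD27, rose from 1248 ± 456 to 5440 ± 353, a log2 difference of 2.14 ± 0.28 (SE, adjusted p = 0.00401 in limma). The tested TNF-family ligand genes of the fixed lists did not pass as rising in limma: Ltb fell, and Tnfsf11, Lta, Tnf, Fasl, Cd40lg and Tnfsf10 did not pass, with log2 differences from -0.18 for Fasl to 1.43 for Tnfsf11. When genes were grouped by the first letters of their symbols into 84 families of at least 8 tested genes, 3 of 8 Tnfrsf genes rose (Tnfrsf8, Tnfrsf9 and Tnfrsf18) and 0 fell, and camera gave adjusted p = 0.0139, against adjusted p = 0.972 with an estimated correlation. Of 38 genes whose symbols begin with Cd and a number, Cd6, Cd68, Cd70 and Cd200 rose and 0 fell (adjusted p = 0.000851 by camera, and adjusted p = 0.972 with an estimated correlation). Altogether 7 of the 84 families passed camera with the preset correlation. The others were St, which was higher (adjusted p = 0.024), and Rpl, Rps, Zfp and Mrpl, which were lower (adjusted p = 0.019, 0.0415, 0.0415 and 0.0415), and none passed with an estimated correlation. Shared letters do not always mean related genes.

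Some of the genes that passed in limma were neighbours in the genome. In the gene order of the assembly GRCm38.p6, 4 pairs of neighbouring tested genes had both members called in the same direction, namely Ccl5 with Ccl9, Ccl9 with Ccl3, Ccl3 with Ccl4, and Cd6 with Tmem109. Random orders of the calls among 5578 placed genes gave 1.33 such pairs on average and up to 8 (one-sided permutation p = 0.0465, 10000 draws). The rising chemokine gene Ccl1 was in none of them. Tmem109 rose by 1.82 ± 0.32 on the log2 scale (SE, adjusted p = 0.0178 in limma). Without anergic array 2 neither Tmem109 (1.57, adjusted p = 0.112) nor Ccl5 (1.24, adjusted p = 0.215) passed in limma, nor did they without the intensity trend (adjusted p = 0.0749 and 0.134). The pairs Ccl5 with Ccl9 and Cd6 with Tmem109 are then lost, and the permutation was not repeated without them.

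The rise of the 12 genes named as rising most could be technical in several ways. As the source of the rise itself, the choice of pseudocount was argued against. With the pseudocount at the array median, 12 of the 12 passed in limma. Which genes make up the 12 does depend on it. At that setting Scg2 was at 1.66 and Hipk2 at 2.14, while Ccl3, outside the 12, was at 2.55 or more in every alternative. Macrophages or dendritic cells carried into the anergic samples may bring chemokine transcripts, yet the median log2 difference of their 12 tested markers was -0.0506 (95% bootstrap interval -0.415 to 0.396). Their abundant transcript Lyz2 was at 129.1 and 73.3 in control and at 11.7 and 11.4 in anergic cells, Cd74 was at 1775 and 1990 against 1983 and 2928, and Cd14 at 764.1 and 931.9 against 684.4 and 858.2. Cd68 was the only one of the 12 that passed in limma (2.31, adjusted p = 0.0103), and a dim probe set of Csf1r, below the filter, was at 21.1 and 25.9 in control and at 55.8 and 125.7 in anergic cells. The brighter probe set of Adgre1, also dim and below the filter, was at 24 and 20.2 in control and at 36.4 and 36.9 in anergic cells. Only 12 of the 29 markers with a probe set were tested, and Cd74 and Cd14 were already bright in control cells. The tested markers and Lyz2 argue against such cells as the main source of the rise, while a small share of them is not excluded. A different T cell clone in the anergic samples remains open: receptor segment probe sets above 1000 differed by at most 1.48-fold between groups, but a probe set assigned to Trbv1 was at 7603 and 11282 where another was at 19.1 and 15.6, so the bright ones may not read the variable segment. Anergy itself, the difference named by the design, stays among the explanations and was not tested separately from time since stimulation or culture.

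The lower ribosomal protein genes could reflect a difference between arrays that depends on brightness, since they are among the brightest genes. Lists of 21 genes matched on mean level had a median of -0.164 (95% of them between -0.314 and -0.0355), against -0.515 for the ribosomal genes, at the 0.01 percentile of 10000 lists, the smallest that this number of lists can give. After quantile normalization the percentile was 0.75, with a median of -0.136 against 0.0556 for matched lists. The ribosomal median was thus below that of genes of similar level on both scales, although the matched genes were slightly dimmer (mean log2 of 12.8 against 13.1). The matched genes were drawn singly, while ribosomal genes may vary together. The percentiles therefore cannot decide whether brightness is the whole cause. Control array 2 alone as the source cannot be told apart from a shift in both control arrays: without it 56.8% of the median was kept, and the 95% bootstrap interval of -0.408 to -0.231 reaches past the midpoint of the full value. A change in ribosomal gene expression with anergy remains a hypothesis.

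The fall of the interferon-induced genes also shrank when a single array was left out. Without control array 2 the median was -0.239 (95% bootstrap interval -0.365 to -0.124), over 27 of the 29 genes because Ifit1 and Ifit3 then fell below the filter. This is 41.2% of the median over all 29, or 47.6% of the median over the same 27 genes (-0.503), which leaves open whether that array is the source. A lower response to interferon gamma than to type I interferon would suggest a larger fall of interferon gamma targets. These 10 genes had a mean log2 difference of -0.534 and 7 type I targets one of -1.18, a difference of 0.644 in the opposite direction (95% bootstrap interval -0.00249 to 1.4, exact two-sided permutation p over genes = 0.0897), and genes are not independent replicates. The type I mean rests largely on Ifit1 (-2.80) and Ifit3 (-2.05), the genes that fell below the filter without control array 2. The other type I targets lay between -1.11 and -0.40. The interferon gamma targets were uneven as well. Iigp1, Irgm1, Ifi47 and Igtp lay between -1.62 and -0.85, and Psmb9, Psmb10 and Tap1 between 0.02 and 0.16, with the rest in between. The test therefore did not settle the question. A larger fall on the type I side may hang on that array or on which genes make up each set.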
